A study of Homo sapiens with 16 samples.

How the data were processed

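RNA of cells labelled HCT116 was measured by RNA-seq in 16 libraries of 8 groups, with 2 libraries per group. The groups were formed by 2 shRNA labels and 4 treatments (DMSO, EPZ-5676, HMBA, both compounds). Per the labels' protocols, poly(A) RNA was made into libraries with a stranded TruSeq mRNA kit. The deposited table holds raw counts of reads per gene for all 16 libraries, with 60676 rows named by Ensembl gene identifiers, and the authors' counts are used as deposited. Per the submitters' processing notes, STAR 2.4.0b, Cufflinks 2.1.1, HTSeq 0.6.1p1 and edgeR were used with the hg38 build, with no role given for each tool, and the annotation release and strand setting of the counts are not given in the sources used here. Of the identifiers, 42305 matched a symbol and 18371 did not, and 58503 had a position in GENCODE release 29 on hg38, which gives the coordinates printed. There were 30345 genes with no count in any library, 0 pairs of libraries with identical counts, and 0 rows without a gene name. The 10 most abundant genes took 8.04% to 13.8% of counts and mitochondrial genes 5.70% to 12.2%.

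Samples were grouped by their titles. The planned fit was edgeR 4.0.16 in R 4.3.3 (limma 3.58.1) with a quasi-likelihood F-test on all 16 libraries, a mean for each group, TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. It kept 17625 genes with 8 residual degrees of freedom and served 15 comparisons, which were the knockdown under each of 4 treatments, each of 3 treatments against DMSO for both shRNA labels, and 5 differences between these. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, on 30 lists in the planned fit, with lists of under 3 measured genes left out. All of their 753 entries matched the table. These comparisons, lists, alternatives and rules for naming genes were chosen before the data were examined. Alternatives were RLE scaling, no filter, DESeq2 1.42.0 on the same genes, limma-voom, only the groups compared, the replicate number as a block, and leaving out each library.

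Libraries were compared by Pearson's r of log2 CPM with a prior count of 2. A library was said to stand apart when its r was below 0.9 with every library numbered 2, and libraries with a mean r of at least 0.93 were joined into a profile, both limits set after the correlations were seen. After this, further fits were tried: the planned fit on the 9 libraries that do not stand apart, and fits with additive terms for shRNA, EPZ-5676 and HMBA on the 8 libraries of each replicate number, on the 9, and on all 16 with and without the replicate number as a block. The fit on the 8 libraries numbered 2 (14808 genes, 4 residual degrees of freedom) is the one described at length, because those libraries share a profile, and its results stand beside those of the 8 numbered 1 (16637 genes). Pairwise product terms were added to it, each alone, leaving 3 residual degrees of freedom. Terms for shRNA and EPZ-5676 were also fitted in the 4 libraries numbered 2 with HMBA and in the 4 without, with 1 residual degree of freedom each. The fit on the 8 libraries numbered 2 tested 29 lists, since fibroblast markers had too few measured genes. Pairs of libraries that differ in the tested factor alone gave the number of pairs with a direction, of 4. The biological coefficient of variation was 0.934 over 16 libraries, 0.965 in number 1 and 0.0811 in number 2.

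The rule for named genes took NELFE, NELFA, NELFB, NELFCD, DOT1L, HEXIM1, CDK9, MYC and CDKN1A whatever their values. It added the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 2 CPM in the higher group and no overlap between the groups, leaving out clone, locus and antisense names, and the 5 smallest p-values for a difference. Results for 3 genes are not reported here. As the planned comparisons called no gene, the rule was applied to the 3 added effects and the product terms. For lists, up to 2 members with the smallest p were named for the 6 lists with the smallest camera p per effect, in place of the planned 4 for each list called, and none in the planned comparisons. The condition of no overlap was applied to the 4 libraries of each arm, which favours genes that the other factors move little.

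Levels of single libraries are CPM on totals TMM-scaled over all 16 libraries. Group means with SD in the fits of number 2 are CPM on totals TMM-scaled over those 8. Floors of 3 counts in a library are in CPM on unscaled totals. A fold against a group with 0 counts is a bound against 3 counts over the group. With few counts, the ratio of summed counts, each divided by the summed TMM-scaled library sizes, has an exact binomial interval at 95%. Intervals and floors cover counting error only. The code was tested on simulated counts with 200 changed genes. Within number 2, 85.1%, 91.0% and 100% of genes changed 1.5-fold, 2-fold and 4-fold by HMBA were recovered, 79.1%, 95.5% and 100% by knockdown, 76.1%, 92.5% and 98.5% by EPZ-5676, and 19.4%, 61.2% and 93.9% by a product term. In the 16-library fit of the knockdown under DMSO, 0% was recovered at each size. Figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A single shRNA against NELFE is named in the labels, so off-target effects cannot be separated from those of NELFE.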

Results

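Poly(A) RNA was sequenced in 16 libraries, all labelled as HCT116, a human colorectal carcinoma cell line. The cells carried a control shRNA (shCTL) or an shRNA against NELFE (shNELFE), and were given DMSO, EPZ-5676, HMBA or both compounds. NELFE is the RNA-binding subunit of negative elongation factor (NELF), which holds RNA polymerase II in a pause near promoters. EPZ-5676, also called pinometostat, inhibits the histone methyltransferase DOT1L. HMBA, hexamethylene bisacetamide, is a small polar compound known to release the elongation kinase P-TEFb from its inhibitory complex and to induce HEXIM1. The 8 groups held 2 libraries each, which the labels number 1 and 2. Total counts per library ran from 13428893 to 21319666 over 60676 genes, with 17867037 to 21319666 in the libraries numbered 1 and 13428893 to 16354111 in those numbered 2. A floor of 3 counts in a library corresponds to 0.141 to 0.223 counts scaled to library totals (CPM), and floors and intervals cover counting error only. Doses and treatment times were not in the labels, and nothing states whether libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

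NELFE (ENSG00000204356, hg38 chromosome 6, 31952087 to 31959110) was examined in every library, since its level tests the labels. Levels of single libraries here and below are CPM on totals TMM-scaled over all 16 libraries. In the libraries numbered 2, NELFE stood at 75.1 CPM in shCTL DMSO, 78.6 in shCTL EPZ-5676, 70.9 in shCTL HMBA and 67.2 in shCTL with both compounds. The libraries labelled shNELFE and numbered 2 held 18.1 CPM under DMSO, 20.9 under EPZ-5676, 17.2 under HMBA and 14.5 under both. In the libraries numbered 1, NELFE stood at 244 CPM in the library labelled shCTL DMSO, 99.6 in shCTL EPZ-5676, 133 in shCTL HMBA and 279 in shCTL with both compounds. The libraries labelled shNELFE and numbered 1 held 146 CPM under DMSO, 93.0 under EPZ-5676, 81.2 under HMBA and 12.5 under both. NELFE in 3 of the 4 libraries labelled shNELFE and numbered 1 was thus above its level in every library labelled shCTL and numbered 2. On totals without TMM scaling this held for shNELFE DMSO alone. All 3 still stayed above the libraries labelled shNELFE and numbered 2. Groups are named by their labels throughout, and directions drawn from the libraries numbered 1 carry that doubt.

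HEXIM1 (ENSG00000186834, chromosome 17, 45148502 to 45152101), the P-TEFb inhibitor that HMBA induces, ranged from 364 to 374 CPM in the 4 libraries numbered 2 with HMBA and from 64.6 to 79.9 in the 4 without it. In the 7 libraries numbered 1 other than shNELFE with both compounds, HEXIM1 was 43.2 to 76.1 CPM, whether the label named HMBA or not. VIM, the intermediate filament gene of mesenchymal cells, ranged from 0.106 to 1999 CPM in the 7 and from 2.83 to 8.25 in the 9. CDH1, the epithelial cadherin, ranged from 0.101 to 1592 CPM in the 7 and from 78.0 to 204 in the 9, and the epithelial adhesion gene EPCAM from 14.6 to 235 against 293 to 596. These marker genes were chosen after the library correlations were seen. Across genes, which are not independent replicates, Pearson's r of log2 CPM between a library of the 7 and a library of the 9 was 0.735 to 0.805 (63 pairs). The 7 fell into 3 profiles with r of 0.991 to 0.992 inside a profile (5 pairs) and 0.741 to 0.918 between profiles (16 pairs). shCTL DMSO and shCTL with both compounds formed a profile, shNELFE DMSO and shCTL HMBA formed another, and shCTL EPZ-5676, shNELFE EPZ-5676 and shNELFE HMBA formed the third. The marker ranges split by profile. In the first profile VIM was 1786 and 1999 CPM, CDH1 0.103 and 0.101, and the keratin gene KRT19, also chosen afterwards, had 0 and 1 counts. In the other libraries of the 7, VIM was 0.106 to 1.16 CPM, CDH1 575 to 1592 and KRT19 2102 to 4564. KRT19 was 708 to 1202 CPM in the 9. Correlations among the 8 libraries numbered 2 were 0.939 to 0.991, and 0 of the 16 libraries had the other library of its group as its closest. The 2 libraries of shNELFE with both compounds, neither of which is among the 7, had an r of 0.982. Its replicate 2 had an r of 0.988 with shCTL with both compounds and 0.988 with shNELFE HMBA, both replicate 2. The libraries numbered 2 hold 1 library of each group, so fits of them do not measure the spread between libraries of a group.

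**Figure D1:**
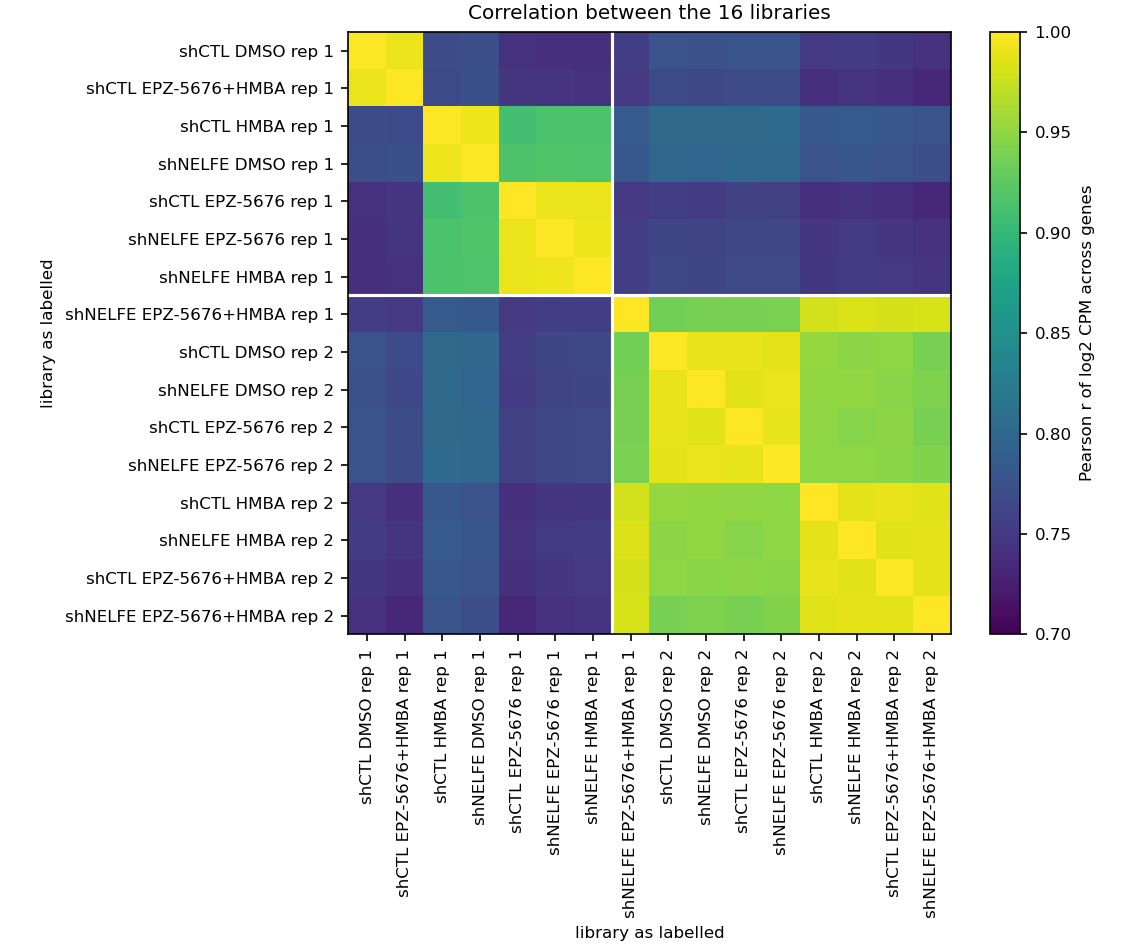
Pearson's r of log2 CPM across genes between each pair of the 16 libraries, labelled by group and replicate number, with 7 libraries numbered 1 above and left of the white lines; colour gives r. The 8 libraries numbered 2 and shNELFE with both compounds replicate 1 form a block with r of at least 0.936, and the other 7 libraries fall into 3 small blocks with r of at least 0.991.

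**Figure D2:**
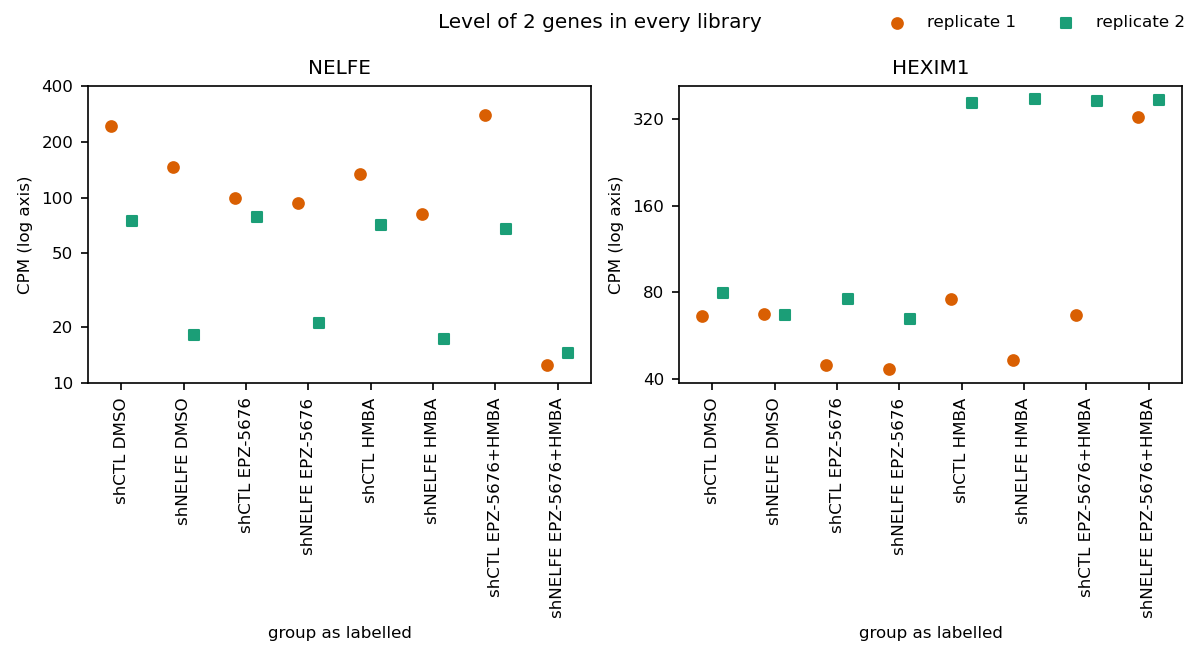
TMM-scaled CPM on log axes of NELFE and HEXIM1 in each of the 16 libraries, by labelled group, with circles for replicate 1 and squares for replicate 2. Each point is a library and no error is drawn. HEXIM1 in replicate 2 is 364 to 374 CPM with HMBA and 64.6 to 79.9 without it, and 43.2 to 76.1 in 7 libraries numbered 1.

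The comparison of shNELFE with shCTL under each compound asks which mRNAs depend on NELFE. NELFE itself was lower by label under DMSO, with a log2 fold change of -0.96 (SE 1.12), under EPZ-5676 with -0.65 (SE 1.12), under HMBA with -1.05 (SE 1.13) and under both compounds with -3.68 (SE 1.24). Each had an edgeR adjusted p of 1, and under DMSO, EPZ-5676 and HMBA the NELFE difference was smaller than its own standard error. When a library was left out, NELFE ran under DMSO from -3.14 (without shNELFE DMSO replicate 1) to 0.13 (without shCTL DMSO replicate 1), and under EPZ-5676 from -2.09 (without shNELFE EPZ-5676 replicate 1) to 0.058 (without its replicate 2). It ran under HMBA from -2.58 (without shNELFE HMBA replicate 1) to -0.33 (without its replicate 2), and under both from -4.38 (without shCTL with both compounds replicate 2) to -2.32 (without its replicate 1). CDKN1A, the cell cycle inhibitor p21, had a log2 fold change of 1.94 (SE 1.28) under DMSO. It was 340 CPM in shNELFE and 21.6 in shCTL in replicate 1, whose libraries belong to different profiles, and 166 and 110 in replicate 2. With edgeR, 0 of 17625 genes passed in any of the 4 comparisons, while 216, 11, 45 and 291 genes had an unadjusted p under 0.05 under DMSO, EPZ-5676, HMBA and both, against 881 expected by chance. DESeq2 called 98, 2, 16 and 125 genes in the same order, and limma-voom called 0 in each. With the replicate number as a block, edgeR called 0, 0, 0 and 7. Of the 30 fixed gene lists, 0 held with an estimated correlation or with fry in any of the 4. In simulated counts with the spread of these 16 libraries, 0% of genes changed 4-fold under DMSO were recovered. Without the 7 libraries described above, every group but shNELFE with both compounds has 1 library, so the only residual degree of freedom comes from the 2 libraries of that group. That fit called 11, 9, 19 and 21 genes with edgeR, and says nothing about the spread in other groups.

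The comparison of each compound with DMSO asks which mRNAs respond to DOT1L inhibition, to HMBA and to both. HEXIM1 had a log2 fold change of 1.59 (SE 1.01) for HMBA in shCTL cells, 1.58 (SE 1.01) for both compounds in shCTL cells, 1.65 (SE 1.02) for HMBA in shNELFE cells and 2.37 (SE 1.04) for both in shNELFE cells. For HMBA it ran from 0.058 without shCTL HMBA replicate 2 to 2.31 without its replicate 1 in shCTL cells, and from -0.53 without shNELFE HMBA replicate 2 to 2.47 without its replicate 1 in shNELFE cells. MYC, the growth-promoting transcription factor, had -2.26 (SE 1.65) and -3.10 (SE 1.71) for HMBA in shCTL and shNELFE cells. In shCTL cells MYC was 170 CPM with HMBA and 178 with DMSO in replicate 1, and 33.1 and 798 in replicate 2. In shNELFE cells it was 26.8 and 185 in replicate 1, and 68.8 and 634 in replicate 2. For both shRNA labels the replicate 1 libraries compared belong to different profiles. The shCTL and shNELFE EPZ-5676 libraries of replicate 1 share the profile of shNELFE HMBA replicate 1 and are labelled without HMBA. MYC in both was below 68.8 CPM too. The replicate 1 fall in shNELFE cells therefore cannot be told apart from a difference between profiles. CDKN1A had 2.71 (SE 1.31) for HMBA in shCTL cells, with 302 CPM against 21.6 in replicate 1, across different profiles, and 561 against 110 in replicate 2. DOT1L, the target of EPZ-5676, had 0.27 (SE 0.64) and -0.47 (SE 0.64) for EPZ-5676 in shCTL and shNELFE cells. The edgeR adjusted p was 1 for these genes except for HEXIM1 with both compounds in shNELFE cells, where it was 0.841. With edgeR, 0 genes passed in any of the 6 comparisons. In shCTL cells 227, 287 and 41 genes had an unadjusted p under 0.05 for EPZ-5676, HMBA and both, and 48, 84 and 677 in shNELFE cells. DESeq2 called 101, 89 and 6 genes in shCTL and 13, 17 and 92 in shNELFE cells, and limma-voom 0 in each, and 0 of 30 lists held with an estimated correlation or with fry. Without the 7 libraries, in arms of 1 library but for shNELFE with both compounds, whose 2 libraries give all of the spread, edgeR called 20, 1603 and 1788 genes in shCTL and 10, 1564 and 3059 in shNELFE cells, with 1 residual degree of freedom.

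The differences between those comparisons ask whether NELFE knockdown alters the response to a compound, and whether EPZ-5676 and HMBA add up on the log2 scale. The HEXIM1 response to HMBA differed between shNELFE and shCTL cells by a log2 of 0.06 (SE 1.40), and the MYC response by -0.83 (SE 2.24). The departure of HEXIM1 from additive compounds was 0.27 (SE 1.40) in shCTL and 1.04 (SE 1.40) in shNELFE cells. With edgeR, 0 genes passed for any of the 5 differences, and 65, 266 and 10 genes had an unadjusted p under 0.05 for the change in response to EPZ-5676, HMBA and both. For departure from additive compounds 936 genes did so in shCTL and 272 in shNELFE cells. DESeq2 called 20, 32, 5, 243 and 33 genes in that order, and limma-voom 0 in each, and 0 of 30 lists held with an estimated correlation or with fry. With no filter on low counts edgeR called 210 genes for the departure in shCTL cells. That departure adds DMSO and both compounds, whose replicate 1 libraries form 1 profile. It subtracts EPZ-5676 and HMBA, whose replicate 1 libraries belong to the other profiles. Its counts therefore cannot be told apart from a difference between profiles. Without the 7 libraries, with the spread again from that pair alone, the counts were 12, 11, 5, 16 and 13.

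The 8 libraries numbered 2, with 1 library in each group, were then fitted with additive terms for shRNA, EPZ-5676 and HMBA, a choice made after the library profiles and the planned results were seen. Each effect sets 4 libraries against 4 that also differ in the other factors, so an SD over 4 libraries includes those factors, and departures from additivity enter the residual. Group means from here on are CPM on library sizes TMM-scaled over these 8 libraries. HMBA raised HEXIM1 to 388 ± 7.22 CPM (SD, n = 4) from 75.3 ± 7.62, which is 5.16-fold (log2 2.37, SE 0.07), with an edgeR adjusted p of 4.31e-12 and higher levels in 4 of 4 pairs. MYC (chromosome 8, 127735434 to 127741434) fell to 51.2 ± 19.95 from 772 ± 83.8 CPM, a log2 fold change of -3.97 (SE 0.20) with an edgeR adjusted p of 4.95e-10 in 4 of 4 pairs. CDKN1A rose to 885 ± 368 from 129 ± 35.9 CPM (log2 2.73). DOT1L fell to 29.7 ± 4.57 from 87.4 ± 8.38 CPM (log2 -1.56). NELFA, a NELF subunit, fell to 19.9 ± 1.87 from 51.5 ± 5.25 (log2 -1.37), while NELFCD (-0.33), the P-TEFb kinase CDK9 (-0.30) and NELFE (-0.22) fell less. NELFB, with -0.11 and an edgeR adjusted p of 0.171, was lower in 3 of 4 pairs and did not pass.

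Among called genes whose 4 libraries with HMBA did not overlap the 4 without it, the 8 largest rises included TENT5C, a poly(A) polymerase gene, at 94.97 ± 27.0 against 1.60 ± 0.922 CPM, and genes close to absent without HMBA. The ratio of summed counts per summed TMM-scaled library size was 282 for the thyroglobulin gene TG (95% interval 77.7 to 2336), 202 for the betaine transporter gene SLC6A12 (35.7 to 8012), 144 for RPL3L (48.8 to 700.4), 81.6 for ASTL (42.7 to 179) and 76.9 for MOBP (20.9 to 642). The adrenergic receptor gene ADRA2A was at least 45.5-fold higher and the ribosomal protein pseudogene RPS4XP21 at least 57.5-fold higher, against a floor of 3 counts over the 4 libraries without HMBA, where both had 0 counts. Reads of RPS4XP21 and RPL3L may be shared with their paralogs, so those 2 are uncertain. The 8 largest falls among such genes included the phosphodiesterase gene PDE4B, at 4.50 ± 1.04 against 178 ± 46.0 CPM, the WNT ligand gene WNT16, at 3.19 ± 1.47 against 116 ± 42.4, and the morphogen gene BMP4, at 15.2 ± 2.75 against 435 ± 94.3. ZBED2 fell with a log2 fold change of -5.31 and FJX1 with -5.04. The ratio of summed counts, scaled in the same way, was 78.1 for HK2-DT, 53.2 for CAVIN2 and 29.3 for MAB21L4, all lower with HMBA. With edgeR, 10443 of 14808 genes passed, 5161 higher and 5282 lower, of which 1679 rose and 1988 fell at least 2-fold. Unscaled totals shifted the median of all genes by -0.23 and left 32.8% of calls higher, against 49.4% with TMM scaling. In the 8 libraries numbered 1 the same fit called 0 of 16637 genes with edgeR, with 3 at an unadjusted p under 0.05. Of the 9870 genes called in number 2 and tested there, 6323 (64.1%) had the same sign. DESeq2 and limma-voom were not run on those 8. As the profiles in number 1 do not follow the labels, each effect there sets profiles against each other. Shares of signs in number 1, here and below, therefore do not test whether an effect of number 2 repeats.

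Cytosolic ribosomal protein mRNAs rose with HMBA in 65 of 65 measured genes (65 adjusted over the list alone), with a median log2 fold change of 0.48, among them RPL12 (0.71) and RPS20 (0.79). Camera gave that list an adjusted p of 1.65e-08, and adjusted p = 0.477 with an estimated correlation. The mitochondrially encoded mRNAs rose in 13 of 13 genes (13 adjusted over the list alone), with MT-ND2 (1.02) and MT-ND4 (1.00) of respiratory complex I, a camera adjusted p of 9.02e-06 and adjusted p = 0.380 with an estimated correlation. The mitochondrial share of all counts, a common sign of RNA or cell quality, was 8.87% to 10.1% with HMBA and 6.12% to 6.90% without it in these 8 libraries. Of 31 immediate early genes, which respond to signals without new protein synthesis, 23 rose and 6 fell, with IER5 at 140 ± 4.31 against 30.8 ± 3.49 CPM and ATF3 at 53.8 ± 3.87 against 8.59 ± 1.30. The count was also 23 and 6 adjusted over the list alone, with a camera adjusted p of 2.15e-05 and adjusted p = 0.345 with an estimated correlation. Of 16 replication-dependent histone genes, 12 rose (13 adjusted over the list alone), among them H2BC5 at 33.2 ± 8.91 against 2.94 ± 1.098 CPM and H2AC6 (log2 2.63), with adjusted p = 0.345 with an estimated correlation. Most histone mRNAs lack a poly(A) tail and histone genes are near-identical, so that group is uncertain in a poly(A) library. Of 4 metallothionein genes, which bind zinc and copper, 3 rose (3 adjusted over the list alone), with MT1E (1.64) and MT2A (1.62), and adjusted p = 0.306 with an estimated correlation.

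Of 34 MYC target and ribosome biogenesis genes, 25 fell and 6 rose with HMBA, with the RNA polymerase I subunit gene POLR1B at 35.3 ± 5.01 against 151 ± 13.3 CPM and URB2 at 11.5 ± 2.34 against 90.8 ± 5.52. The list had a median of -0.65 and adjusted p = 0.345 with an estimated correlation. Of 11 HOXA cluster and MEIS1 genes, developmental regulators that depend on DOT1L in some leukaemias, 9 fell and 0 rose, with a median of -2.30 and adjusted p = 0.345 with an estimated correlation. Of 35 G1/S and DNA replication genes, 23 fell and 6 rose, with adjusted p = 0.477 with an estimated correlation. Among stress and metabolic lists, 22 of 30 ATF4 and unfolded protein response genes rose and 5 fell, 18 of 25 cholesterol synthesis genes rose and 3 fell, 16 of 29 p53 targets rose and 8 fell, and 12 of 21 heat shock genes rose and 4 fell, each list with adjusted p = 0.345 with an estimated correlation. Of 31 hypoxia and glycolysis genes 22 rose and 5 fell, with adjusted p = 0.581 with an estimated correlation. All lists in this paragraph had the same counts when adjusted over the list alone. Of 12 leukocyte and erythroid markers, which belong to other cell types, 4 were measured and 3 rose (3 adjusted over the list alone), with the integrin gene ITGAM at 11.7 ± 5.34 against 0.270 ± 0.0638 CPM, CD68 (0.58) and the globin gene HBA1 (2.02), which has a near-identical copy. Their median was 1.30, with a camera adjusted p of 0.0719, a fry adjusted p of 0.000440 and adjusted p = 0.345 with an estimated correlation, and the other 8 were too low to be tested. Camera called 13 of 29 lists for HMBA, 0 held with an estimated correlation, and fry, which asks only whether a list's own genes move on balance one way, called 25. For the metallothionein list the estimated correlation was 0.0166, near the preset 0.01, yet the camera adjusted p went from 2.53e-05 to 0.306. Not passing with an estimated correlation therefore does not by itself show correlation among the genes of a list. Medians, means and tests of the lists called for HMBA, knockdown or EPZ-5676 shared a sign within each list, and those medians kept it under RLE, upper quartile and no scaling. Without scaling the cholesterol synthesis median for HMBA was 0.08, and 10 heat shock genes rose while 9 fell.

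**Figure D3:**
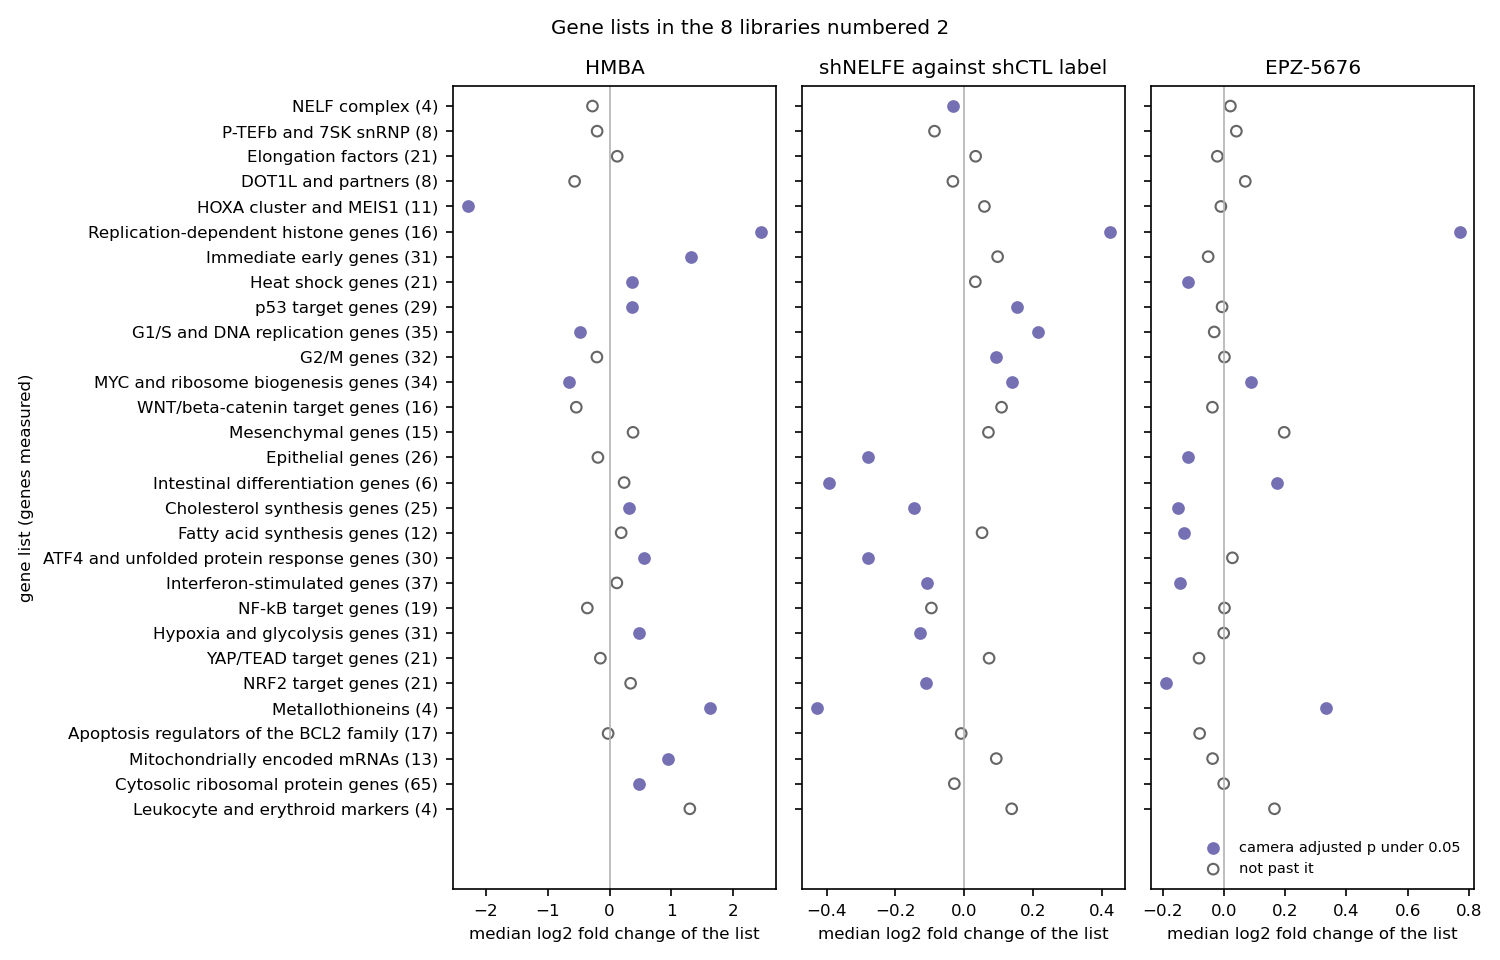
Median log2 fold change of each fixed gene list for HMBA, the shNELFE label and EPZ-5676 in the 8 libraries numbered 2, with the number of measured genes in brackets; filled points passed camera with a preset correlation, 0 lists passed with an estimated correlation, and the 3 panels have different x scales. HMBA medians run from -2.30 for the HOXA list to 2.46 for histone genes, while the knockdown median is -0.28 for ATF4 genes and the EPZ-5676 median is 0.77 for histone genes.

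For NELFE knockdown in the same 8 libraries, NELFE was at 18.6 ± 2.85 CPM in those labelled shNELFE and 76.4 ± 5.82 in those labelled shCTL (SD, n = 4), a log2 fold change of -2.04 (SE 0.08) with an edgeR adjusted p of 1.99e-08, lower in 4 of 4 pairs. B3GALT4, a galactosyltransferase gene on chromosome 6 (33277132 to 33284832), rose to 9.81 ± 1.51 from 0.528 ± 0.286 CPM (log2 4.16, SE 0.26, edgeR adjusted p of 1.97e-06, 4 of 4 pairs). CDKN1A rose by a log2 of 0.86 and the NELF subunit gene NELFCD by 0.30, while NELFA, NELFB, HEXIM1, CDK9, MYC and DOT1L did not pass. Among called genes whose 4 and 4 libraries did not overlap, the next largest rises were SPTSSB (0.73), NCAL1 (0.70), SPA17 (0.70), the mitochondrial carrier gene UCP2 (0.64), the receptor ligand gene GAS6 (0.61), PIGQ (0.59) and SNHG10 (0.59), the last an antisense gene and uncertain because the strand setting of the counts is not stated. LCN2, an iron-scavenging secreted protein gene, fell to 1.88 ± 0.749 from 8.43 ± 0.482 CPM (log2 -2.19). Among such genes, falls followed for SULT1A3 (-1.89), which has a near-identical copy, the acute phase gene SERPINA3 (-1.74), the glucose transporter gene SLC2A3 (-1.60), WNT7A (-1.50), the interferon-induced IFITM1 (-1.50) and DAPP1 (-1.45). With edgeR, 1940 genes passed, 832 higher and 1108 lower, of which 55 rose and 83 fell at least 2-fold. The count was 353 when shNELFE with both compounds replicate 1 was added (9 libraries), which brings in the spread between 2 libraries of a group. It was 0 in the libraries numbered 1, where 306 genes had an unadjusted p under 0.05 and 1022 of 1883 called genes (54.3%) had the same sign. It was 1023 without shCTL DMSO, 1090 without shCTL HMBA, 1226 without shNELFE with both compounds, 1240 without shCTL with both and 1243 without shNELFE EPZ-5676, each replicate 2.

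Of 30 ATF4 and unfolded protein response genes, 14 fell and 1 rose in libraries labelled shNELFE (17 and 2 adjusted over the list alone), among them PCK2 at 28.0 ± 7.38 against 58.4 ± 11.3 CPM and the asparagine synthetase gene ASNS at 181 ± 89.5 against 352 ± 133. The list had a median of -0.28, a camera adjusted p of 2.37e-16 and adjusted p = 0.213 with an estimated correlation. Of 26 epithelial genes 12 fell and 0 rose (20 and 1 adjusted over the list alone), with the protease inhibitor gene SPINT1 (-0.89) and the tight junction gene OCLN (-0.70), and adjusted p = 0.289 with an estimated correlation. Of 35 G1/S genes 15 rose and 0 fell (21 and 0 adjusted over the list alone), with the nucleotide synthesis gene TYMS (0.38), and adjusted p = 0.289 with an estimated correlation. Of 25 cholesterol synthesis genes 11 fell and 1 rose (12 and 1 adjusted over the list alone), with INSIG1 (-0.73) and STARD4 (-0.83), and adjusted p = 0.213 with an estimated correlation. Of 34 MYC target and ribosome biogenesis genes 9 rose and 0 fell (11 and 0 adjusted over the list alone), with ODC1 (0.40) and NCL (0.27), and adjusted p = 0.468 with an estimated correlation. The NELF complex list of 4, whose test is led by NELFE itself, had 1 gene higher and 1 lower (1 and 1 adjusted over the list alone), and adjusted p = 0.224 with an estimated correlation. Camera called 14 of 29 lists, fry 8, and 0 held with an estimated correlation.

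For EPZ-5676 in the same 8 libraries, GRAMD1B, a sterol transporter gene, rose to 28.7 ± 9.53 from 6.63 ± 3.67 CPM (SD, n = 4), a log2 fold change of 2.16 (SE 0.15) with an edgeR adjusted p of 1.30e-05, higher in 4 of 4 pairs. Among called genes whose 4 and 4 libraries did not overlap, NHS rose by a log2 of 1.90, the atypical cadherin gene FAT4 by 1.38, the lipid phosphatase gene PLPP3 by 1.29, the orphan nuclear receptor gene NR4A2 by 1.26, HLF by 1.07, SPON1 by 1.05 and the semaphorin receptor gene NRP2 by 1.01. WWTR1, which encodes the transcriptional coactivator TAZ, fell to 49.0 ± 11.2 from 87.3 ± 21.8 CPM (log2 -0.83, edgeR adjusted p of 1.54e-05, 4 of 4 pairs). The other largest falls among such genes were those of GPER1 (-1.35), ARHGAP24 (-0.99), ANKRD22 (-0.83), the transcription factor gene ETS1 (-0.76), the viral RNA sensor gene RIGI (-0.74), GULP1 (-0.73) and ODAD2 (-0.72). DOT1L, at 57.9 ± 30.5 against 59.2 ± 37.1 CPM, had an edgeR adjusted p of 0.862, was higher in 2 of 4 pairs, and like the other genes of the list NELFE, NELFA, NELFB, NELFCD, HEXIM1, CDK9, MYC and CDKN1A did not pass. With edgeR, 563 genes passed, 201 higher and 362 lower, of which 40 rose and 6 fell at least 2-fold. The count was 30 in the 9 libraries. It was 2141 in the 4 libraries without HMBA alone, with 520 of the 563 among them, and 461 in the 4 with HMBA alone, with 217 of the 563 among them. Those 2 fits set 2 libraries against 2 with 1 residual degree of freedom, so their counts do not measure a difference in response. The product term that tests this difference passed for 5 genes. The count for EPZ-5676 was 0 in the libraries numbered 1, where 71 genes had an unadjusted p under 0.05 and 280 of 534 called genes (52.4%) had the same sign. It was 210 without shNELFE EPZ-5676, 220 without shCTL DMSO, 261 without shNELFE DMSO, 261 without shNELFE with both compounds, 277 without shCTL HMBA and 308 without shCTL EPZ-5676, each replicate 2, and 1077 with no filter on low counts.

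Of 16 replication-dependent histone genes, 6 rose and 0 fell with EPZ-5676 (9 and 0 adjusted over the list alone), with H2AC6 at 18.2 ± 15.9 against 9.81 ± 8.13 CPM and H2BC21 at 10.3 ± 9.99 against 4.93 ± 5.39. The list had a median of 0.77, a camera adjusted p of 4.58e-10 and adjusted p = 0.240 with an estimated correlation. Of 25 cholesterol synthesis genes 7 fell and 0 rose (8 and 0 adjusted over the list alone), with SQLE (-0.65) and MSMO1 (-0.53), a camera adjusted p of 4.66e-10 and adjusted p = 0.130 with an estimated correlation. Of 21 heat shock genes 4 fell and 0 rose (6 and 0 adjusted over the list alone), with the cochaperone genes BAG3 (-0.46) and DNAJB1 (-0.43), and adjusted p = 0.240 with an estimated correlation. Of 4 metallothionein genes 3 rose (3 adjusted over the list alone), with MT1X (0.58) and MT1E (0.35), and adjusted p = 0.130 with an estimated correlation. Of 26 epithelial genes 4 fell and 0 rose (8 fell and 1 rose adjusted over the list alone), with DSC2 (-0.52) and OCLN (-0.47), and adjusted p = 0.667 with an estimated correlation. Of 12 fatty acid synthesis genes 3 fell (4 adjusted over the list alone), among them ELOVL6 (-0.41) and ME1 (-0.40), and adjusted p = 0.130 with an estimated correlation. The HOXA cluster and MEIS1 list did not pass for EPZ-5676. Camera called 10 of 29 lists, fry 5, and 0 held with an estimated correlation.

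A product term asks whether the HMBA response differed between shRNA labels within the 8 libraries numbered 2. ADM, the gene of the vasodilator peptide adrenomedullin, averaged 85.3 ± 12.5 CPM (SD, n = 2) with neither, 70.2 ± 1.81 with shNELFE alone, 17.7 ± 0.536 with HMBA alone and 80.4 ± 4.65 with both, a product term of 2.46 on the log2 scale (SE 0.16, edgeR adjusted p = 3.82e-06). ARC, an activity-regulated immediate early response gene, averaged 6.48, 6.19, 57.2 and 329 CPM in that order, the epithelial transcription factor gene ELF3 80.4, 31.4, 77.1 and 79.9, MYC 834, 710, 34.2 and 68.1, and the phosphatase gene DUSP2 24.5, 19.97, 7.52 and 20.7. With edgeR, 36 genes passed, 34 higher and 2 lower, and the count was 2 in the 9 libraries, 159 with no filter on low counts and 58 with DESeq2. It was 19 without shNELFE EPZ-5676, 19 without shCTL HMBA, 23 without shCTL EPZ-5676, 63 without shNELFE HMBA and 92 without shNELFE with both compounds, each replicate 2, and 0 in the libraries numbered 1, where 159 genes had an unadjusted p under 0.05. Simulated product terms in these libraries gave 10.8% false calls, and simulated HMBA, knockdown and EPZ-5676 effects 9.36%, 5.67% and 4.30%, against the 5% aimed at. Each was simulated once with the spread estimated in number 2, which leaves out the spread between libraries of a group.

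**Figure D4:**
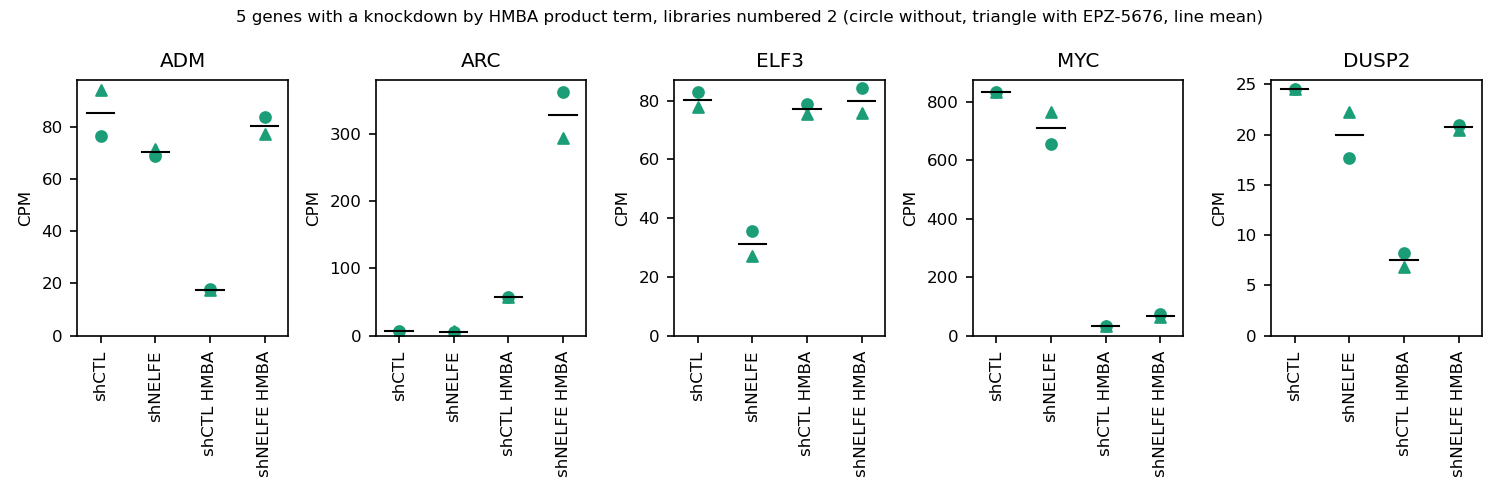
TMM-scaled CPM on linear axes from 0 of the 5 genes with the smallest p for the knockdown by HMBA product term, in the 8 libraries numbered 2; circles are libraries without and triangles libraries with EPZ-5676, and lines are means of 2 libraries. ADM averages 17.7 CPM with HMBA alone and 80.4 with HMBA and the shNELFE label, and ARC averages 57.2 and 329.

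For EPZ-5676 by HMBA, PLPP3 averaged 9.26 CPM with neither, 38.9 with EPZ-5676 alone, 9.91 with HMBA alone and 12.2 with both (n = 2 each), a product term of -1.77 (SE 0.19, edgeR adjusted p = 0.00203), so that its rise with EPZ-5676 rested on the libraries without HMBA. The amino acid transporter gene SLC38A2 averaged 473, 300.2, 111 and 122 CPM, and the pseudogene MSL3P1 25.8, 16.9, 13.1 and 19.4. With edgeR 5 genes passed, 2 higher and 3 lower. The remaining 2 are the unnamed ENSG00000279809, with group means of 0.0330, 8.27, 2.80 and 0.0380 CPM, and ENSG00000258465, with 0, 2.16, 2.26 and 2.89. The count was 2 with RLE scaling, 23 with DESeq2, 184 with no filter and 0 in the 9 libraries, and 13, 29, 19 and 15 without shCTL EPZ-5676, shNELFE EPZ-5676, shCTL HMBA and shNELFE HMBA replicate 2. It was 0 in the libraries numbered 1, where 3672 genes had an unadjusted p under 0.05, against 832 expected by chance. There the term sets the profile of shCTL DMSO and shCTL with both compounds against others, so it cannot be read as an effect of the compounds. For knockdown by EPZ-5676, edgeR called 0 genes, with 269 at an unadjusted p under 0.05, and DESeq2 called 1, limma-voom 0 and edgeR with no filter 31. Leaving out a library gave up to 7 genes, with 1 without shCTL DMSO, 4 without shNELFE DMSO, 2 each without shCTL EPZ-5676, shCTL HMBA or shNELFE HMBA, and 7 without shCTL with both compounds, each replicate 2.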

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

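Among the tests in this part, the comparison of correlations across the HMBA label, the counts of genes gained or lost in a profile and the scaling test of the product term were chosen only after the result was seen; the product terms themselves were also added after the library profiles were known.

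The knockdown by HMBA product term was past the edgeR threshold for 36 genes in the 8 libraries numbered 2, which marks a difference in HMBA response between the shRNA labels by a test of the difference itself. The 5 with the smallest p had product terms of 2.46 (ADM), 2.58 (ARC), 1.41 (ELF3), 1.22 (MYC) and 1.77 (DUSP2) on the log2 scale. The EPZ-5676 by HMBA product term was past the threshold for 5 genes, with -1.77 for PLPP3, 0.78 for SLC38A2 and 1.17 for MSL3P1.

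In 7 of the 8 libraries numbered 1, expression stood apart from the other 9 libraries, in 3 profiles that do not follow the labels. Thinning every library to 13428893 counts left a median r of 0.769 between the libraries of a group (0.763 before), which argues against depth. Each profile joined libraries with and without HMBA in their labels, which argues against the labelled HMBA as the source of the profiles. The lowest r of those 4 pairs was 0.991, above the 0.952 that was the highest of 16 such pairs in number 2. As the profiles were formed from these same correlations, a high r inside them is no separate support. The labelled shRNA and EPZ-5676 were not tested in this way. Each profile held genes at 10 CPM or more in all of its libraries and with no count in the other 9, with 72, 50 and 61 genes. Of 1235 genes at 100 CPM or more in each of the other 9 libraries, 8, 14 and 11 had 3 counts or fewer in every library of a profile. Both counts argue against a library batch of the same cells as the whole cause, but as they come from libraries already chosen for standing apart, they support no other source. For HMBA in number 2, 0 genes were at 10 CPM or more in the 4 libraries with it and without counts in the 4 others, and 0 the reverse. Beside the 72, 50 and 61 genes, this argues against a difference between cultures no larger than the HMBA response as the whole cause. Another cell source, mislabelled libraries and a larger difference between cultures stay open, as no test here decides among them. No biological explanation was tested.

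Of the 36 genes with a knockdown by HMBA product term, 34 were higher in cells with both perturbations than additive log2 effects give. The median product term of the 36 was 0.986, and RLE, upper quartile or no scaling shifted the median of all genes by 0.042 at most, which argues against library scaling as its source. Without scaling 29 genes passed. The slope of HMBA responses in shNELFE on those in shCTL libraries was 0.973 over 10443 genes, which argues against a larger HMBA response throughout. The immediate early list held 5 of the 36 genes. Its camera adjusted p was 4.32e-17 with the preset correlation and 0.480 with an estimated correlation. As the 2 settings disagree, whether that list moved as a group was not decided. A biological interaction stays open as an untested hypothesis, on 2 libraries per combination that differ in EPZ-5676. In the simulation 10.8% of product term calls were false, but it leaves out the spread between libraries of a group. In the 9 libraries, which bring in that spread for 1 group, 2 genes passed.

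All 65 ribosomal protein mRNAs measured were higher with HMBA in number 2. The list median was 0.483 with TMM scaling and lowest without scaling, at 0.252, where 65 of 65 were still higher and 60 passed the threshold, which argues against library scaling as the whole cause. Random lists matched on merged exon length and abundance had medians between 0.383 and 0.537 in their middle 95%. The ribosomal median of 0.483 lay at their percentile 75.6, so exon length and abundance may account for the rise. The match was loose, with a median exon length of 1897 in matched genes against 1384, and a median of 660 CPM against 817. A specific response of these genes was therefore not shown.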

How the results depend on the processing

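In this part, all additive fits, all product terms and all fits of the 9 libraries that do not stand apart were chosen only after the result was seen, and the other alternatives were planned. The planned 16-library fit called 0 genes in all 15 comparisons, and so did RLE scaling, limma-voom, fits of the compared groups alone and every fit that left out a library, where a lone library was assumed to vary like the other groups. The cause was not tested for any value that follows.

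DESeq2, which gave no adjusted p for up to 3759 genes, called 98, 2, 16 and 125 genes for knockdown under DMSO, EPZ-5676, HMBA and both, 101, 89 and 6 for EPZ-5676, HMBA and both in shCTL cells, and 13, 17 and 92 in shNELFE cells. For the differences it called 20, 32, 5, 243 and 33, and no filter called 210 for non-additivity in shCTL cells. In shCTL cells that difference sets the profile of DMSO and both compounds replicate 1 against the other profiles, so its counts cannot be read as non-additivity alone. In the 9 libraries the planned fit, with 1 residual degree of freedom that comes from the 2 shNELFE libraries with both compounds while all other groups have 1 library, called 11, 9, 19 and 21 for knockdown, 20, 1603 and 1788 in shCTL cells, 10, 1564 and 3059 in shNELFE cells and 12, 11, 5, 16 and 13 for the differences. Deviations from group means correlated at over 0.1 in 24 of 28 pairs of groups (0.065 to 0.961, median 0.431), and 15 of 16 libraries were closest to a library of their own number. The libraries numbered 2 share a profile, but r between libraries numbered 1 was 0.741 to 0.992 (median 0.773), so no structure common to number 1 was seen. As 4 pairs of groups did not reach 0.1 and the labels name no shared source, the numbers were not taken to pair the libraries. With the replicate number as a block the planned fit called 7 genes for knockdown under both compounds, 1 for EPZ-5676 in shCTL cells, 1 for both compounds in shNELFE cells, 2 for non-additivity in shCTL and 5 in shNELFE cells, and changed no other count of genes.

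Camera with a preset correlation called lists in the planned fit as follows, with the range when a library was left out: 9 for knockdown under DMSO (6 to 11), 1 for knockdown under EPZ-5676 (1 to 6), 7 for knockdown under HMBA (4 to 8), 8 for knockdown under both (3 to 13), 9 for EPZ-5676 in shCTL cells (1 to 10), 11 for HMBA in shCTL cells (9 to 13) and 10 for both in shCTL cells (5 to 13). It called 6 for EPZ-5676 in shNELFE cells (4 to 10), 7 for HMBA in shNELFE cells (5 to 8), 12 for both in shNELFE cells (6 to 12), 7 for the difference in response to EPZ-5676 (5 to 12), 10 for the difference in response to HMBA (5 to 12), 5 for the difference in response to both (1 to 8), 7 for non-additivity in shCTL cells (5 to 10) and 4 for non-additivity in shNELFE cells (2 to 12). With an estimated correlation or fry, 0 lists passed in each. Counts moved over 1.5 times, with the number after a label its replicate, for knockdown under EPZ-5676, to 2 without shCTL DMSO 1, 2 without shCTL DMSO 2, 4 without shCTL EPZ-5676 1, 4 without shCTL EPZ-5676 2, 6 without shNELFE EPZ-5676 1, 6 without shNELFE EPZ-5676 2 and 2 without shCTL both 1, for knockdown under HMBA, to 4 without shCTL HMBA 1, for knockdown under both, to 3 without shCTL both 1 and 13 without shNELFE both 2 and for EPZ-5676 in shCTL cells, to 1 without shCTL DMSO 1 and 5 without shCTL EPZ-5676 1. They also moved for both in shCTL cells, to 5 without shCTL both 2, for EPZ-5676 in shNELFE cells, to 10 without shNELFE EPZ-5676 1 and for both in shNELFE cells, to 7 without shCTL DMSO 2, 6 without shNELFE DMSO 2, 6 without shCTL both 1 and 7 without shNELFE both 1. Of the differences, they moved for the difference in response to EPZ-5676, to 12 without shCTL EPZ-5676 2 and 11 without shNELFE EPZ-5676 1, for the difference in response to HMBA, to 5 without shCTL DMSO 2, 6 without shNELFE DMSO 1, 6 without shCTL HMBA 1 and 6 without shNELFE HMBA 2, for the difference in response to both, to 2 without shCTL DMSO 1, 8 without shCTL both 1 and 1 without shNELFE both 1 and for non-additivity in shNELFE cells, to 12 without shNELFE DMSO 2, 2 without shNELFE HMBA 1, 7 without shNELFE HMBA 2 and 9 without shNELFE both 2.

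Within number 2 the HMBA count (10443) was 9392 to 11060 over RLE scaling, no filter, DESeq2, limma-voom, the 9 libraries and leaving out a library, which gave 9716 to 10220. The knockdown count (1940) was 1023 to 2002 and the EPZ-5676 count (563) 210 to 604 when a library was left out, the knockdown by HMBA term (36) 19 to 92, the EPZ-5676 by HMBA term (5) 4 to 29 and the knockdown by EPZ-5676 term (0) 0 to 7. The 9 libraries gave 353 for knockdown, 30 for EPZ-5676, 2 for knockdown by HMBA and 0 for EPZ-5676 by HMBA, and all of the 353 and 30 genes were also called in number 2. No filter gave 1077 for EPZ-5676, 159, 31 and 184 for the product terms of knockdown by HMBA, knockdown by EPZ-5676 and EPZ-5676 by HMBA, and DESeq2 gave 58, 1 and 23. RLE scaling gave 2 for EPZ-5676 by HMBA, and the 4 libraries without HMBA alone gave 2141 for EPZ-5676, against 461 in the 4 with HMBA alone. With 1 residual degree of freedom in each of those 2 fits, their counts do not measure a difference in response. The additive fits of number 1, of all 16 libraries and of all 16 with the replicate block called 0 genes for each effect and product term. For the EPZ-5676 by HMBA term in number 1, 3672 genes had an unadjusted p under 0.05 with edgeR, against 832 expected by chance. Leaving out a library left 14 to 18 lists past camera for HMBA (13 with all 8), 13 to 16 for knockdown (14) and 8 to 12 for EPZ-5676 (10).

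For the 36, 27 and 28 named genes called for HMBA, knockdown and EPZ-5676, 463 of 571, 379 of 484 and 369 of 501 values under the alternatives kept sign and threshold, 101, 75 and 116 lost the threshold, and 7, 30 and 16 turned sign. In fits with the 7 libraries that stand apart, differences between profiles enter each effect. Signs in those fits do not test whether an effect of number 2 repeats. In the libraries numbered 1, signs turned for HMBA in CAVIN2 0.082, ZBED2 1.69, PDE4B 2.53, BMP4 0.15, MYC 0.21, RPL12 -0.0015 and H2AC6 -0.31, and for knockdown in NCAL1 -0.92, UCP2 -0.74, GAS6 -2.36, PIGQ -0.94, SULT1A3 0.53, SERPINA3 3.40, IFITM1 0.96, NELFB -0.46, DOT1L -0.14, HEXIM1 0.64, MYC -0.93, ASNS 0.91, SPINT1 0.88, OCLN 0.48, TYMS -0.38, INSIG1 0.35 and STARD4 0.31. They also turned for EPZ-5676 in GPER1 0.67, ARHGAP24 0.63, ANKRD22 4.54, WWTR1 0.24, ETS1 2.12, GULP1 0.54, ODAD2 1.75, NELFE -0.51, NELFA -0.19, NELFCD -0.32, DOT1L -0.60, HEXIM1 0.43, CDKN1A 0.52, H2AC6 -0.39, DNAJB1 0.71 and ME1 0.32, and for the knockdown by HMBA term in MYC -1.86 and DUSP2 -1.03, and for the EPZ-5676 by HMBA term in PLPP3 1.67.

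In all 16 libraries, signs turned for knockdown in NCAL1 -0.17, UCP2 -0.71, GAS6 -0.48, PIGQ -0.69, SERPINA3 2.13, IFITM1 0.58, NELFB -0.31, HEXIM1 0.10, MYC -0.57, SPINT1 0.10, TYMS -0.015 and INSIG1 0.037, and for EPZ-5676 in GPER1 0.58, NELFE -0.42, NELFA -0.11, NELFCD -0.21, DOT1L -0.35, HEXIM1 0.042, CDKN1A 0.13 and DNAJB1 0.0089. They also turned for the knockdown by HMBA term in MYC -0.73. In all 16 with the replicate block, signs turned for knockdown in NCAL1 -0.13, UCP2 -0.041, GAS6 -0.60, PIGQ -0.18, SERPINA3 0.013, WNT7A 0.31, DAPP1 0.00032, NELFB -0.22, HEXIM1 0.21, MYC -0.76 and TYMS -0.0059, and for EPZ-5676 in ANKRD22 1.36, ODAD2 0.14, NELFE -0.31, NELFA -0.057, NELFCD -0.10, DOT1L -0.33, HEXIM1 0.10, CDKN1A 0.19, DNAJB1 0.13 and DSC2 0.00088. They also turned for the knockdown by HMBA term in MYC -1.23. In the 9 libraries, signs turned for EPZ-5676 in NELFE -0.050 and NELFB 0.0042.

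In the libraries without HMBA alone, signs turned for knockdown in NELFB -0.10 and MYC -0.24, and for EPZ-5676 in NELFB 0.017, DOT1L -0.13 and MYC 0.10. In those with HMBA alone, signs turned for knockdown in HEXIM1 0.033, and for EPZ-5676 in NELFE -0.14, NELFCD -0.0073 and HEXIM1 0.0085. With limma-voom, signs turned for EPZ-5676 in MYC 0.035. When single libraries were left out, log2 changes that turned sign in some fit ranged, over all 16 libraries, for knockdown under DMSO in NELFE -3.14 to 0.13, for knockdown under EPZ-5676 in NELFE -2.09 to 0.058 and for HMBA in shNELFE cells in HEXIM1 -0.53 to 2.47. Within number 2 the ranges were, for EPZ-5676, NELFE -0.060 to 0.065, HEXIM1 -0.059 to 0.025, MYC -0.21 to 0.19, NELFCD -0.0083 to 0.086, DOT1L -0.029 to 0.11 and NELFB -0.11 to 0.010; for knockdown, NELFB -0.038 to 0.072. Within number 2, none of these genes had passed in all 8 libraries for the effect it is listed under, while the MYC log2 change, knockdown in libraries numbered 2, passed at an adjusted p of 0.00145 in the 4 libraries without HMBA. Depth limits genes near 3 counts per library (0.141 to 0.223 CPM), for which folds are bounds or wide ratios.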

Other observations

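Among the tests in this part, the one on genes around NELFE and the divisions of the libraries numbered 1 were chosen only after the result was seen.

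Further lists fixed in advance were called by camera in the libraries numbered 2, and none of them passed with an estimated correlation. In libraries labelled shNELFE, 3 of 6 intestinal differentiation genes fell (4 adjusted over the list alone; adjusted p = 0.213 with an estimated correlation), 2 of 4 metallothionein genes fell (4 adjusted over the list alone; adjusted p = 0.213) and 5 of 16 histone genes rose (8 adjusted over the list alone; adjusted p = 0.468). Of 31 hypoxia and glycolysis genes 11 fell and 3 rose (11 and 5 adjusted over the list alone; adjusted p = 0.573 with an estimated correlation), and of 29 p53 targets 5 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.289). Of 37 interferon-stimulated genes 7 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.522 with an estimated correlation), of 21 NRF2 targets 7 fell and 2 rose (9 and 2; adjusted p = 0.522), and of 32 G2/M genes 5 rose (7 adjusted over the list alone; adjusted p = 0.573). With EPZ-5676, 3 of 21 NRF2 targets fell and 1 rose (13 and 2 adjusted over the list alone; adjusted p = 0.380 with an estimated correlation), 3 of 37 interferon-stimulated genes fell (5 adjusted over the list alone; adjusted p = 0.747), 2 of 34 MYC targets rose (2 adjusted over the list alone; adjusted p = 0.731) and 1 of 6 intestinal genes rose (2 adjusted over the list alone; adjusted p = 0.431).

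Genes called for 2 effects in the libraries numbered 2 were counted by direction beside the number that independent calls would give. HMBA and knockdown shared 356 genes higher in both (290 if independent), 377 lower in both (395) and 750 in opposite directions (683). HMBA and EPZ-5676 shared 84 higher (70.1), 181 lower (129) and 179 opposite (198), and knockdown and EPZ-5676 shared 23 higher (11.3), 66 lower (27.1) and 52 opposite (35.4). The 3 effects are estimated from all 8 libraries in a balanced layout, so they share no control group, but genes with little spread are called more often for each effect, so an excess is not evidence of a shared effect.

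Other divisions of the 8 libraries of a number into 4 and 4 were compared with the real ones, 33 each with the real one included, in the same model for the division alone with the 2 other factors kept. In number 2, 1 of 33 gave as many genes as HMBA (10443, highest other 0), 1 of 33 as many as knockdown (1940, highest other 1) and 1 of 33 as many as EPZ-5676 (563, highest other 11), the smallest share that 33 divisions allow. In the other divisions the real effect of that factor adds to the residual, which lowers their counts. In number 1 the real divisions gave 0 genes, so 33 of 33 gave as many by construction, with highest others of 2, 14 and 2.

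An effect on genes around NELFE was a hypothesis because B3GALT4, also on chromosome 6, had the largest rise with the shNELFE label among called genes with a mean of at least 2 CPM in the higher group and no overlap between the 4 and 4 libraries, with clone, locus and antisense names left out. Within 2 Mb on each side of NELFE 12 of 117 genes tested were called for knockdown (10.3%), against 13.1% elsewhere, with a two-sided Fisher exact p of 0.411, so no excess was seen there, although genes are not independent replicates and the test leaves single genes such as B3GALT4 open. A dependence of the response on gene span was a further hypothesis. Spearman's rho across genes, which are not independent replicates, between span and fold change ran over the 4 matched pairs from -0.068 to 0.062 for HMBA, -0.192 to 0.069 for knockdown and -0.206 to 0.019 for EPZ-5676. The values closest to 0 were -0.0067, 0.013 and 0.019, and the sign differed between pairs for each effect, so no dependence on span held in all pairs.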
